A study of Homo sapiens with 2 samples.

How the data were processed

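RNA-seq of 2 human lung cancer cell lines was used, with 1 library for each line. PC9 is a lung adenocarcinoma line that carries an activating EGFR deletion and is sensitive to EGFR tyrosine kinase inhibitors (EGFR-TKI). MTAC-P is a line derived from PC9 that resists such inhibitors, per the labels. Total RNA was extracted with Trizol and libraries followed standard Illumina procedures, per the labels' protocols. Both cultures were grown in DMEM with serum, per the labels' protocols, which give no inhibitor treatment at the time of harvest. Each library was assigned to its line from the record of the sample it belongs to, since the value columns are headed by short codes that are not the line names. The series text speaks of triplicates, but each line has 1 column of values, and whether cultures were pooled is not given in the sources used here.

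Reads were processed with Trim Galore, TopHat and Cufflinks and the build was hg38, per the submitters' processing notes, which give no versions here; the annotation release is not given in the sources used here. The authors deposited 1 value per transcript, taken here as FPKM (fragments scaled to transcript length and to the library's mapped fragments) because the submitters' processing notes name Cufflinks. The tables do not name the unit. They hold no counts, intervals or status column, so the depth of each library is unknown and no interval for a gene's value can be given. An exact 0 can be a failed estimate, and such genes are described as listed at 0.

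Each table has 65536 lines including its header, the row limit of an older spreadsheet format, and its 65535 transcript IDs are sorted and end at number 437205. Transcripts with later IDs were not analysed here. Of the listed IDs, 55396 (84.5%) were in GENCODE release 29 for GRCh38, the assembly that hg38 names, which supplied coordinates, transcript lengths and GC content. Of its 83064 coding transcripts 37887 (45.6%) were listed. At least 1 coding transcript was listed for 17945 of 19684 coding genes, and all of them for 5832. A gene's value is therefore the sum of its listed transcripts, and a difference can be a difference between transcripts of that gene. Spreadsheet software had turned 25 symbols (104 transcripts) into dates, and these were named in no result.

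Values of transcripts with the same symbol were summed, giving 30843 symbols. Genes with a mean of at least 1 FPKM over both libraries were compared, 11435 in all, of which 10570 were protein-coding by the biotypes in the tables. The measure was log2((MTAC-P + 1)/(PC9 + 1)), called the log2 ratio, which understates the difference of low genes because of the pseudocount of 1. Genes at 2-fold or more on this scale were counted. With no replicate libraries there is no replicate check, no p-value and no standard error, and genes are not replicates.

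There were 32 gene lists with 924 members, of which 14 had no symbol in the tables. For each list with at least 5 members compared, the percentile of its median log2 ratio was taken among 10000 random lists of the same size matched on mean level in 20 bins. A list stood apart at or below 2.5 or at or above 97.5. This describes these 2 libraries and is not a test of the lines. The genes named were the 15 highest and the 15 lowest log2 ratios among genes with a mean of at least 5, up to 4 members per list at 2-fold or more (or, with none, the 2 most abundant), and 18 genes fixed by name. Unnamed, non-coding and read-through symbols were left out, and some genes that the rule takes are not reported here. The lists, the rule for named genes, the thresholds and most alternatives were chosen before the data were examined. Genes outside that rule are named in a few places, as other members of a list or as examples chosen after their values were seen.

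The alternatives were a pseudocount of 0.1 or 5, a common sum, centring, equal upper quartiles, no filter or a mean of at least 5, symbols on 1 line only, 4-fold or 1.5-fold, coding genes only and unmatched random lists. Added after seeing the data were scaling without mitochondrial genes, genes with all coding transcripts listed, removal of the GC trend in 50 bins, and leaving out chromosome 1. Neighbouring coding genes were also grouped into 404 blocks of 25 along each chromosome, and block medians were set against 1000 shuffles of the genes. Intervals of medians are order-statistic intervals of at least 95% coverage over genes, and the interval of a share of blocks is a Wilson interval. They describe the spread over genes or blocks in these libraries, not the spread between cultures.

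The steps were tested on simulated data for this comparison, with 11399 genes compared and a log2 SD of 0.4 in each library. This SD was set by hand, was the same for all genes and was not estimated from these libraries. The rates below hold for that setting only. Of genes raised 4-fold 97.0% were counted as higher, and of genes lowered 4-fold 89.1% as lower. Of unchanged genes 4.73% reached 2-fold. Of 100 lists of 25 unchanged genes 7 lay beyond the limits, and of 100 lists with 8 of 25 genes raised 4-fold 53 reached the upper limit. Of 10 blocks given a shift of 0.4 among 403, 9 lay above the upper limit, and 6.20% of blocks lay beyond the limits with no shift. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.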

Results

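The transcriptomes of the lung adenocarcinoma line PC9 and of MTAC-P, a line derived from it that resists EGFR tyrosine kinase inhibitors, were compared to ask which genes differ between a sensitive parent and its resistant derivative. Each line had 1 library, so no difference below has a replicate check. The listed FPKM values summed to 693444 in PC9 and 685082 in MTAC-P. Values of 1 or more were given for 19073 transcripts in PC9 and 18575 in MTAC-P, and the number of reads behind them is unknown. Mitochondrial transcripts made up 23.5% of the sum in PC9 and 20.3% in MTAC-P.

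By list medians, MTAC-P had higher levels of NF-kB and cytokine genes and of mesenchymal genes than PC9, and lower levels of NRF2 targets and drug metabolism genes. PI3, which encodes the elastase inhibitor elafin (chromosome 20, 45174876 to 45176544), stood at 95.7 FPKM in PC9 and 1729 in MTAC-P, a log2 ratio of 4.16. LCN2, the iron-carrier protein lipocalin 2 (chromosome 9, 128149071 to 128153455), stood at 337 and 1449 (2.10). In the other direction, S100A4, a calcium-binding protein linked to cell motility (chromosome 1, 153543613 to 153550136), stood at 222 and 16.8 (-3.65), and the aldo-keto reductase AKR1B10 at 621 and 178 (-1.79). EGFR itself (chromosome 7, 55019021 to 55211628) stood at 196 and 239 (0.28).

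Of 11435 genes compared, 398 were at least 2-fold higher in MTAC-P and 490 at least 2-fold lower, together 7.77%. The median log2 ratio was -0.02, and 95% of genes lay between -1.27 and 1.17. Across genes the libraries correlated with Pearson's r of 0.95 and Spearman's rho of 0.94, where genes are not independent replicates. Of the 30 gene lists compared, 6 stood apart as higher and 5 as lower in MTAC-P, where 1.5 would be apart by chance with independent lists. Of coding genes with a mean of at least 5, 10.6% of the 464 whose longest listed transcript was under 1000 nt reached 2-fold, against 4.49% of the 6968 with longer ones, and PI3, SPRR1B and S100A4 are among genes with short transcripts. All coding transcripts were listed for 9 of the 30 genes with the largest differences.

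**Figure D1:**
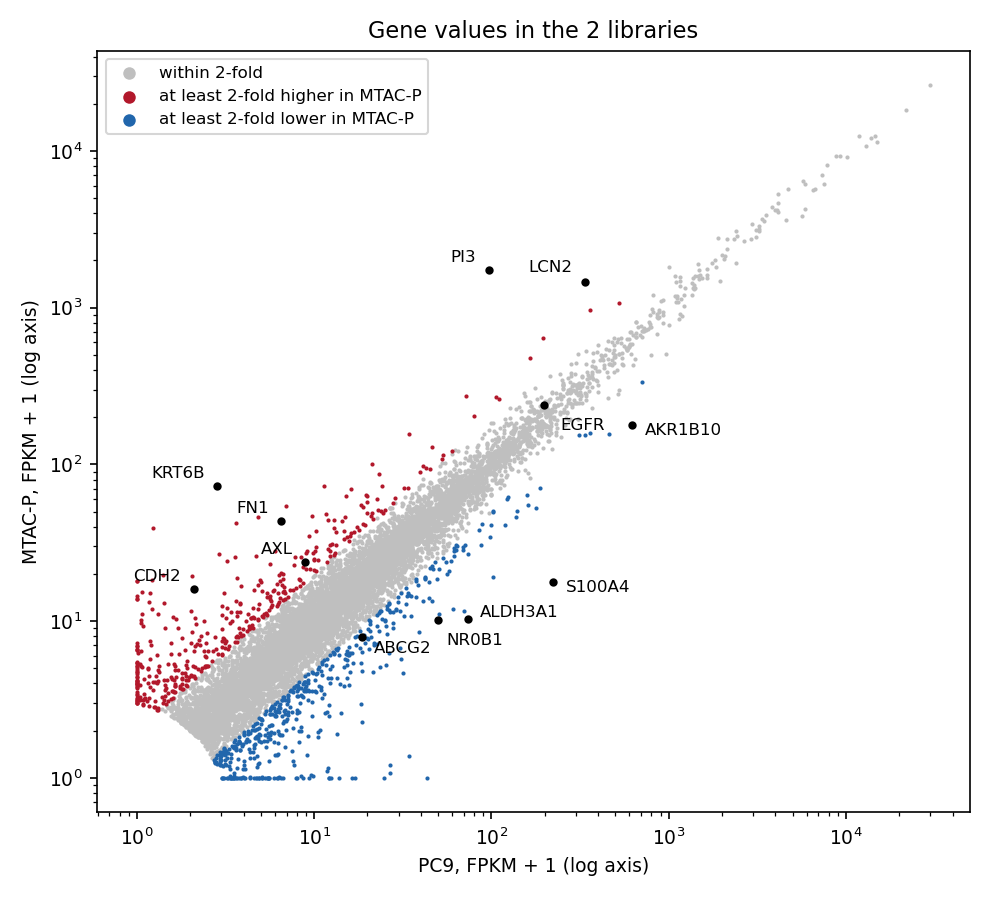
FPKM + 1 of each compared gene in PC9 (horizontal log axis) and MTAC-P (vertical log axis), 1 library each, with genes at 2-fold or more in colour and some named genes in black; a few sex-linked genes are left out of the plot. PI3 and LCN2 lie far above the diagonal and S100A4 and AKR1B10 far below it, while EGFR lies close to it.

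Among the 15 genes with the highest log2 ratios were the epidermal keratins KRT6B (1.84 to 71.7 FPKM, 4.68) and KRT6A (0.221 to 17.2, 3.90), whose sequences are near identical, so that their separate values are uncertain. AOX1, an aldehyde oxidase, had a ratio of 3.80, BCAT1, which transaminates branched-chain amino acids, 3.26, and PDZK1IP1 3.22. The cyclin-dependent kinase gene CDK14 had a ratio of 3.07 and SPRR1B, a protein of the cornified envelope, 2.90. ACY1 (4.15), MAN2B1 (3.83), SIRT7 (3.68), TNIP1 (3.55) and ATP6V0B (3.24) were also in this group. Of the genes named here, KRT6B, KRT6A, PDZK1IP1 and SPRR1B had all their GENCODE coding transcripts listed, and the others had only a part.

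Among the 15 lowest ratios were MGP, a matrix calcification inhibitor (-3.59), PSCA, a cell surface antigen (-2.84), and IGFBP2, which binds insulin-like growth factors (69.4 to 10.6, -2.61). AGR2, a protein disulfide isomerase of mucus-secreting cells, stood at 101 FPKM in PC9 and had a ratio of -2.42. The group also held FAM25A (-3.41), which has close copies, CCS (-3.38), CCNL2 (-2.75), GATSL2 (-2.52), DCXR (-2.46), D2HGDH (-2.43) and MELK (-2.42). GATC stood at 11.1 in PC9 and was listed at 0 in MTAC-P. Of the genes named here FAM25A had all its GENCODE coding transcripts listed, GATSL2 had no match in GENCODE, and the others had only a part listed.

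Genes of NF-kB signalling and cytokines were higher in MTAC-P. Of 27 compared, 26 lay above 0 and 11 were at least 2-fold higher, with none at least 2-fold lower. Their median log2 ratio was 0.94, above the range of matched random lists (percentile 100). IL11, a cytokine of the IL-6 family, stood at 3.70 and 24.9 (2.46), the acute-phase gene SAA1 at 33.2 and 154 (2.18), and TNFAIP3, an NF-kB target that also restrains the pathway, at 13.3 and 42.6 (1.61). SAA1 shares near-identical sequence with SAA2. Of the 16 leukocyte markers only CD68 reached the mean of 1 (22.2 and 28.8, 0.36).

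Mesenchymal genes were higher in MTAC-P, with 7 of 15 at least 2-fold higher, a median of 0.94 and a percentile of 100. CDH2, which encodes N-cadherin (chromosome 18, 27950966 to 28177446), stood at 1.09 and 14.9 (2.93), fibronectin FN1 at 5.54 and 42.4 (2.73), and FSTL1 at 2.69 and 17.9 (2.35). S100A4 was the 1 member at least 2-fold lower. VIM, the intermediate filament gene of mesenchymal cells, stood at 0.831 and 2.52 (0.94). This is below 2-fold only on the scale with the pseudocount of 1, which weighs on such low values. ZEB1 stood at 0.00931 and 0.0523. With no filter on low values the median of 32 mesenchymal genes was 0.16 (percentile 99.96), and with symbols on 1 line only, 5 were left and their median was 0.26 (percentile 89.8). Epithelial genes did not stand apart: of 35 compared, 1 was at least 2-fold higher and 1 at least 2-fold lower, and the median was -0.05. CDH1, which encodes E-cadherin, stood at 35.2 and 35.1. The tight junction gene CLDN3 had a ratio of -1.18 and the splicing factor ESRP2 1.54, from a transcript that is not among its GENCODE coding transcripts. Of the fibroblast and endothelial markers, COL1A1 (0.08), CDH5 (0.24) and ESAM (-0.06) reached the mean of 1.

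Targets of YAP and TEAD, which mediate Hippo signalling, were higher, with 7 of 21 at least 2-fold higher and none at least 2-fold lower (median 0.49, percentile 100). CTGF, a matricellular protein gene, had a ratio of 1.76, TGFB2 1.49 and CRIM1 1.39. AXL, a receptor tyrosine kinase (chromosome 19, 41219203 to 41261766), stood at 7.89 and 22.7 (1.41). Basal and squamous genes were higher, with 3 of 10 at least 2-fold higher, KRT6B, KRT6A and SPRR1B (median 0.48, percentile 99.95). With no filter on low values their median was 0.042 and they did not stand apart. Over all alternatives their median ranged from 0.042 to 1.77. Genes of the unfolded protein and amino acid stress responses had a median of 0.21 (percentile 99.5), with XBP1 (1.01) and STC2 (1.05) at least 2-fold higher of 24; with no filter on low values they did not stand apart (0.13). SPRR1B, PDZK1IP1, TGFB2 and LAMB3 lie on chromosome 1, whose 1122 placed genes had a median log2 ratio of 0.17. Genes that were at least 2-fold lower lie there too, such as S100A4, CCNL2, EPHX1 and GSTM1.

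**Figure D2:**
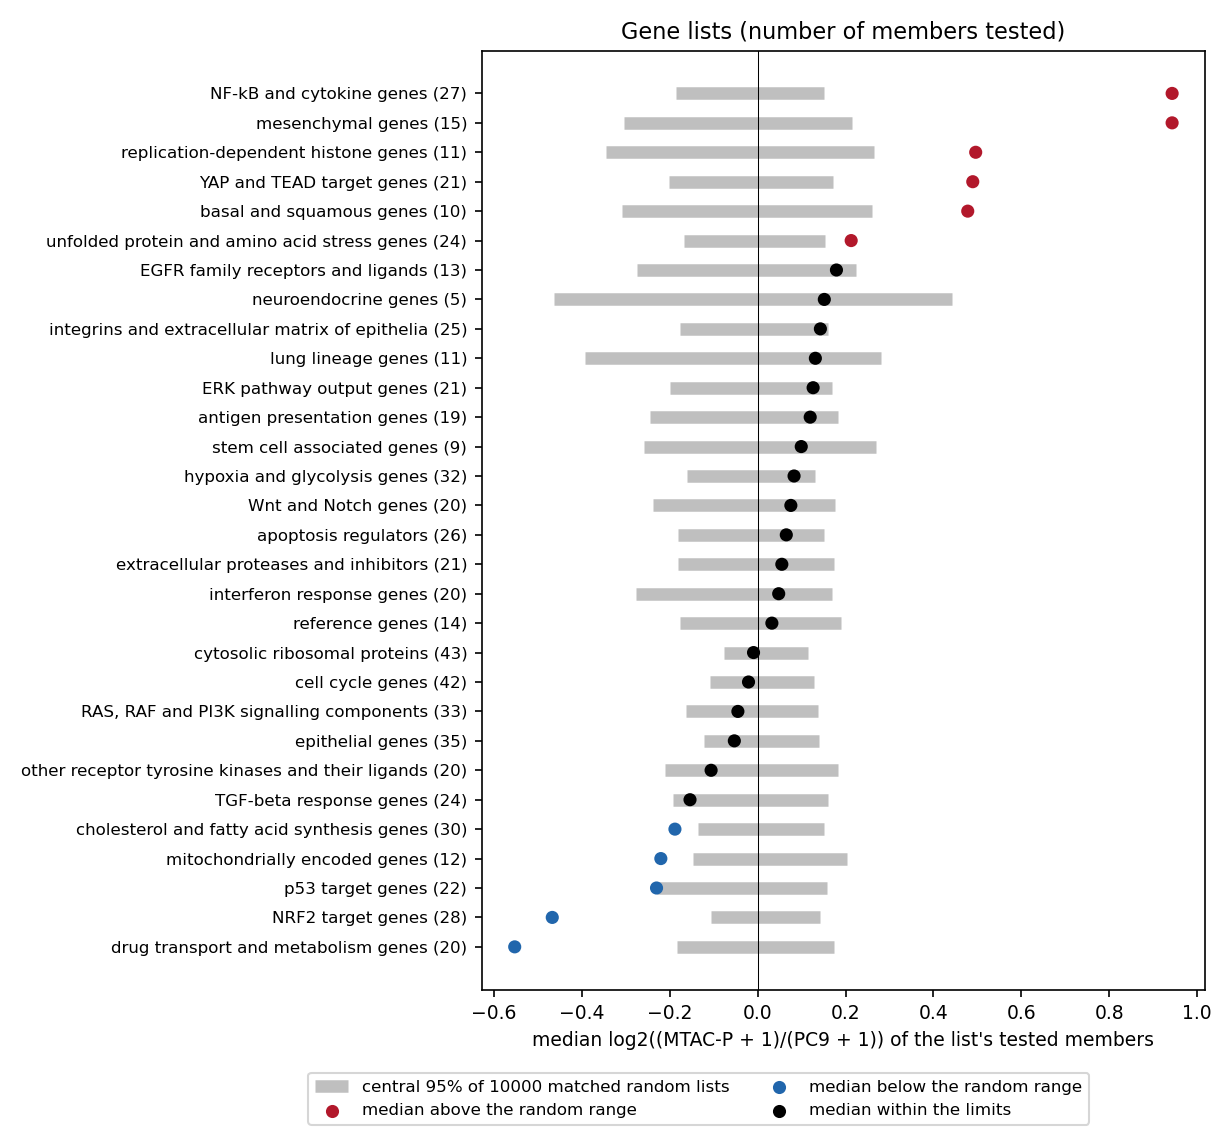
Median log2((MTAC-P + 1)/(PC9 + 1)) of each of the 30 gene lists with at least 5 members compared (points), with the central 95% of 10000 matched random lists (grey bars) and the number of members in parentheses; 1 library per line. NF-kB and mesenchymal genes (both 0.94) lie farthest to the right and drug transport and metabolism genes (-0.55) farthest to the left.

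Targets of NRF2, the regulator of antioxidant genes, were lower in MTAC-P. Of 28 compared, 5 lay above 0, 5 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.47 (percentile 0). Besides AKR1B10, NR0B1 stood at 49.2 and 9.18 (-2.30), the haem oxygenase HMOX1 at 10.9 and 3.34 (-1.46) and the glutathione peroxidase GPX2 at 337 and 153 (-1.13). The exception was AKR1C2 (1.02), which has near-identical copies.

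Genes of drug transport and metabolism were lower, with 7 of 20 at least 2-fold lower, none at least 2-fold higher, and a median of -0.55 (percentile 0). The aldehyde dehydrogenases ALDH3A1 (72.6 and 9.37, -2.83) and ALDH1A1 (4.81 and 1.16, -1.43), the epoxide hydrolase EPHX1 (-1.58) and GSTM1 (-1.52), which has close copies, were among them. ABCG2, a drug efflux pump, stood at 17.6 and 6.97 (-1.22), and ABCB1, another, was listed at 0 in both libraries.

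**Figure D3:**
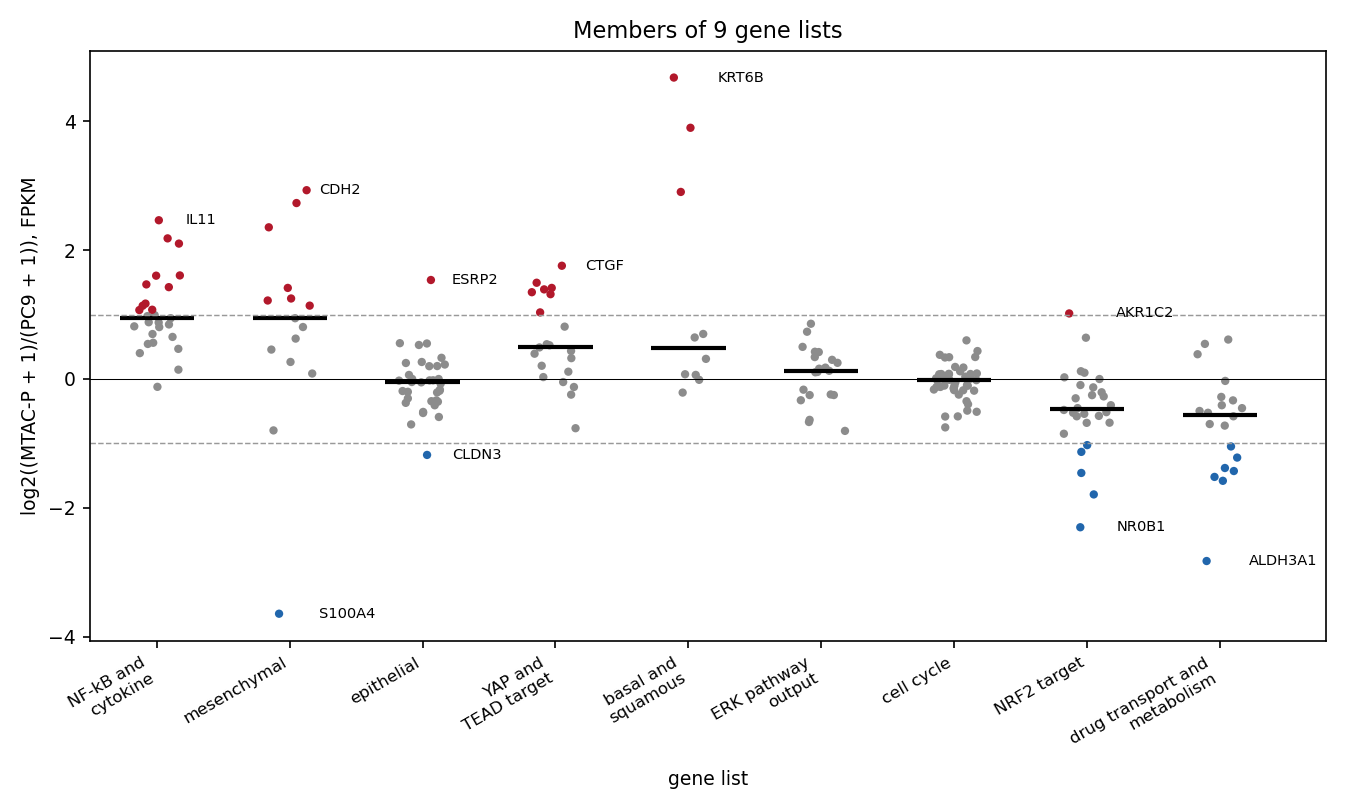
Log2((MTAC-P + 1)/(PC9 + 1)) of the members compared in 9 gene lists (points, 1 library per line), with the list's median (bar), 2-fold limits (dashed lines) and genes at 2-fold or more in red (higher) or blue (lower). NF-kB and mesenchymal genes lie mostly above 0, NRF2 target and drug genes mostly below it, and cell cycle genes close to it with a median of -0.02.

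EGFR family receptors and ligands did not stand apart (median 0.18, percentile 95.1, 13 compared). They stood apart as higher with no filter on low values or with a mean of at least 5 (median 0.35 for the latter). Without chromosome 1, 11 of these genes had a median of 0.02 (percentile 69.9). The ligand gene HBEGF was the 1 member at least 2-fold higher (4.04 and 16.8, 1.82). ERBB3 stood at 17.4 and 9.92 (-0.75) and ERBB2 at 3.16 and 2.87 (-0.10). Output genes of the ERK pathway did not stand apart, with none of 21 at 2-fold and a median of 0.13; the abundant members were CCND1 (0.11) and IER3 (0.34). Among 20 other receptor tyrosine kinase genes and their ligands, with a median of -0.11 and a mean of 0.15, AXL, its ligand GAS6 (1.14) and IGF2 (1.02) were at least 2-fold higher. MET, amplified in some EGFR-TKI resistant tumours, stood at 26.7 and 35.1 (0.38), its ligand HGF at 0.00723 and 0.0314, IGF1R had a ratio of -0.16 and FGFR1 0.08. Among 33 components of RAS, RAF and PI3K signalling (median -0.04) the kinases SRC (8.68 and 1.49, -1.96) and LYN (-2.40) were at least 2-fold lower. LYN had none of its GENCODE coding transcripts listed. NF1 (-0.11) was within 2-fold.

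None of 42 cell cycle genes reached 2-fold (median -0.02); UBE2C stood at 499 and 494 and PCNA at 423 and 459. Of 26 apoptosis regulators (median 0.07) the proapoptotic BAX was at least 2-fold lower (157 and 63.2, -1.30) and BIK higher (1.05), while BCL2L11, which encodes BIM, stood at 11.8 and 11.5. The p53 targets had a median of -0.23 at a percentile of 2.41, close to the limit, with CDKN1A, a cell cycle inhibitor, at 1.59 and BAX lower; several alternatives placed the list within the random range (percentile 6.71 with a pseudocount of 5). Cholesterol and fatty acid synthesis genes were lower by a small amount, with 24 of 30 not above 0 and none at 2-fold (median -0.19, percentile 0.32); ACSL3 stood at 0.17. With symbols on 1 line only, 7 of them were left, at a median of -0.086 and a percentile of 19.0.

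TGF-beta response genes went both ways, with 3 of 24 at least 2-fold higher and 3 lower, a median of -0.15 and a mean of -0.05. INHBA, an activin subunit gene, had a ratio of 2.06, while SMAD6 (-1.58) and ID1 (-1.52) were lower. The sign of this list's median was positive with only genes whose coding transcripts were all listed (0.23). The laminin genes LAMA3 (2.05) and LAMB3 (1.09) were higher and LAMA4 lower (-1.99), in a list of integrins and matrix genes that did not stand apart (0.14, percentile 96.3). That list stayed within the limits in 6 of 12 alternatives and stood apart as higher in the others. Wnt and Notch genes did not stand apart (0.08), with WNT5A (0.167 and 12.2, 3.50) and WNT7A (1.80) at least 2-fold higher. Extracellular proteases and inhibitors had a median of 0.06, with PI3, SLPI (1.53) and ADAM8 (2.03 and 5.07 FPKM) at least 2-fold higher.

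Other lists did not stand apart. Their medians were 0.13 for lung lineage genes (GATA6 1.49), 0.15 for neuroendocrine genes, with a mean of -0.09 (UCHL1 -1.35), 0.05 for interferon response genes (BST2 -0.13, IFITM3 0.35), and 0.12 for antigen presentation genes (2 of 19 at least 2-fold higher, NLRC5 1.08 and PSMB8 1.01, and 1 lower). They were 0.08 for hypoxia and glycolysis genes (STC2 1.05, CA9 -1.11, EGLN3 -1.08, CA12 -1.07; 19 of 32 above 0), 0.10 for stem cell associated genes (HMGA2 1.11, ALDH1A1 -1.43), -0.01 for ribosomal proteins (RPL30 0.18) and 0.03 for reference genes, with a mean of -0.03 (GAPDH -0.23, EEF1A1 0.05). Of the lists that reflect RNA quality, mitochondrially encoded genes were lower (median -0.22, percentile 0.46, none at 2-fold), such as MT-CO2 (-0.23) and MT-ND4L (-0.19). Replication-dependent histone genes were higher (0.50, percentile 99.9), such as HIST1H2BK (1.25) and HIST1H1C (1.18).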

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

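Scaling without mitochondrial genes, genes with all coding transcripts listed, GC removal and leaving out chromosome 1 were chosen after the result was seen. NF-kB, YAP and TEAD, NRF2, drug metabolism and histone genes kept their side of the random range in every alternative that gave a value, with medians from 0.61 to 1.15 for NF-kB, 0.32 to 1.17 for YAP and TEAD, -0.51 to -0.30 for NRF2, -0.60 to -0.43 for drug metabolism and 0.19 to 0.81 for histone genes. The other 6 lists that stood apart lost this in at least 1. The 888 genes at 2-fold became 1344 (775 lower) with a pseudocount of 0.1, 284 (140 higher, 144 lower) with 5, 431 (206, 225) at a mean of at least 5, 396 (182, 214) with symbols on 1 line only, 165 (79, 86) with all coding transcripts listed, 174 (89, 85) at 4-fold and 2307 (1025, 1282) at 1.5-fold; the last 5 test fewer genes or use another threshold. Without mitochondrial genes in the scaling 12468 genes were compared, with 527 higher and 796 lower. This scaling and the common sum raised all values to a larger sum, while the filter and the pseudocount stayed at 1. Both settings therefore also act as a lower filter and a lower pseudocount. The shift between the libraries was small, -0.04 in log2 without mitochondrial genes and 0.02 with the common sum. The p53 list came within the random range with a pseudocount of 0.1 (median -0.26) or 5 (-0.11), no filter (-0.18), all coding transcripts listed (-0.24) or GC removal (-0.14). So did basal (0.042) and unfolded protein genes (0.13) with no filter, mesenchymal (0.26) and cholesterol genes (-0.086) with symbols on 1 line only, and mitochondrial genes (-0.22) against unmatched lists. Integrin and matrix genes stood apart as higher with a common sum (0.24), no filter (0.11), a mean of at least 5 (0.22), symbols on 1 line only (0.47), no mitochondrial genes in the scaling (0.20) and GC removal (0.26). EGFR family genes also stood apart with no filter (0.17) or a mean of at least 5 (0.35). Hypoxia genes (0.18) and Wnt and Notch genes (0.31) did so at a mean of at least 5. At the main minimum mean of 1, Wnt and Notch genes stood apart with GC removal (0.20). At that minimum mean, EGFR family genes lay within the range without chromosome 1 (0.02). RAS, RAF and PI3K genes (-0.40) and proteases (0.77) stood apart with symbols on 1 line only. Antigen presentation genes (0.44) did so with all coding transcripts listed. TGF-beta genes stood apart as lower with no filter (-0.21) but as higher with symbols on 1 line only (0.30) or all coding transcripts listed (0.23). The cause was not tested for any of these lists. Of 1136 values of named genes under alternatives, 1102 kept their side of 2-fold, 31 dropped below it and 3, all of VIM, passed it, and none at 2-fold changed sign. No paired analysis was possible because each line has 1 library, which also rules out leaving out replicates. Counting only genes whose software intervals do not overlap gave no value, since the tables used here hold no intervals. Depth is unknown, so genes near the minimum mean cannot be given a precision.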

Other observations

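Of the tests below, the comparison of symbol families, the leukocyte and fibroblast comparisons, whose criteria were also revised, for leukocytes more than once, the point on single cultures, the share of chromosome 1 genes above the median and the runs of blocks were chosen after the result was seen. Removal of the GC trend and the use of genes with all coding transcripts listed were also added after seeing the data.

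Interleukin genes and their receptors, grouped by symbol, were higher in MTAC-P. Their 27 members had a median log2 ratio of 0.45 (percentile 100), and 5 were at least 2-fold higher and 1 lower. IL1RL1, the receptor of IL-33, stood at 2.59 and 24.5 FPKM (2.83) and IL18R1, a subunit of the IL-18 receptor, at 0.799 and 6.83 (2.12). IL11 and other members are also in the NF-kB and cytokine list. Of 164 symbol families compared 14 stood apart, where 8.2 would by chance if genes were independent. Whether the genes of a family lie together, such as within the runs of blocks below, was not examined. Besides interleukins, those higher were NBPF (median 0.74), WNT (0.31), histone (0.24), EIF (0.14) and SLC genes (0.04). Those lower were UBXN (-0.47), AKR (-0.45), LRP (-0.39), NUDT (-0.29), ARHGAP (-0.24), NDUFA (-0.22), COX (-0.17) and KIAA genes (-0.15). The WNT family holds 9 genes at a percentile of 97.6, while the Wnt and Notch list fixed beforehand did not stand apart.

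Genes on chromosome 1 were higher in MTAC-P over a long stretch. From 46632737 to 201826969, 21 neighbouring blocks with 525 genes lay above the shuffled range, with a median log2 ratio of 0.33 (0.28 to 0.37), and 81.5% of these genes lay above the median of all genes. Of all 1122 placed genes of the chromosome 68.4% did, which restates their higher median and does not test whether a few genes carry it. On chromosome 22, from 17084954 to 30907824, 4 neighbouring blocks with 100 genes had a median of 0.34 (0.26 to 0.39), or 0.41 after removal of the GC trend. CRKL, an adaptor in RAS and PI3K signalling, lies there and stood at 33.8 and 48.4 (0.50), as does XBP1. On chromosome 13, from 27251309 to 94596257, 4 blocks had a median of 0.19, and 1 of them stayed beyond the range after removal of the GC trend. In each of these runs the blocks were joined because they lay above the shuffled range. The raised medians of the runs, their intervals and the 81.5% on chromosome 1 follow from that choice and test nothing.

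Over all chromosomes 21.3% of blocks lay beyond the shuffled range (86 of 404, 49 high and 37 low), which describes the runs and does not test what causes them. On chromosome 1 the tables argue against GC bias, since the median after removing the GC trend was 0.18 (0.15 to 0.22), and against missing transcripts, since genes with all coding transcripts listed had 0.20 (0.17 to 0.25). Over all blocks, the tables argue against GC bias as the only cause of the runs. With the trend removed 15.3% lay beyond the range (12.2% to 19.2%), against 6.20% in the simulated data with no shift. The interval reaches below the 15% set for excluding GC bias, so GC bias as a part of the cause stays open. The share was 21.3% before removal, and on chromosome 19 the blocks below the range went from 8 to 1. A regional change in gene dosage, such as more copies of parts of chromosomes 1 and 22 in MTAC-P, is a hypothesis that stays open. DNA was not analysed here. Shared regulation of neighbouring genes could also give runs. It was not tested, nor was whether it reaches over a stretch as long as that on chromosome 1.

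For the higher NF-kB and cytokine genes, the tables argue against missing transcripts, since the 9 members with all coding transcripts listed had a median log2 ratio of 0.98 (0.70 to 1.43). They also argue against leukocytes in the MTAC-P culture as the cause of the whole pattern, since these would bring all their abundant transcripts, while the median difference of 16 leukocyte markers was -0.141% of that of the list (-0.541% to 5.03%), below the 10% set for it. PTPRC (0.091 and 0.0460 FPKM), LYZ (0.539 and 0.187), CD14 (1.19 and 0.605) and TYROBP (0.129 and 0.104) were lower in MTAC-P. Of the 6 markers that were higher, CD68, already at 22.2 in PC9, had a difference of 70.2% of that of the list, and LAPTM5 went from 0.294 to 1.35. A lasting difference between the lines, which might include higher NF-kB activity, cannot be told apart from the state of the single culture or library. There was 1 library per line. That lasting difference was not tested further. The lists that reflect RNA quality also differed, with medians of -0.22 for mitochondrially encoded genes and 0.50 for histone genes. Their bearing on the NF-kB list was not tested.

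For the higher mesenchymal genes beside near equal epithelial genes, fibroblasts in the culture could raise the list, but the median difference of COL1A1, COL1A2, COL3A1, DCN and LUM was 0.127% of that of FN1 and the highest was 0.738%. Gene length bias is argued against by a percentile of 100 among random lists matched on transcript length (14 members, median 1.04). Missing transcripts cannot be told apart from a difference between the lines, as only 3 members had all coding transcripts listed, with a median of 0.81 and S100A4 at -3.65. A partial mesenchymal state of MTAC-P with CDH1 kept is thus a hypothesis that stays open.

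Genes with under 50% of their coding transcripts listed reached 2-fold 1.13 times as often as genes with all of them listed (0.88 to 1.46). Genes whose longest listed transcript was under 1000 nt did so 2.35 times as often as genes with longer ones (1.77 to 3.13). This ratio met the criterion set beforehand for short transcripts as a source of 2-fold differences, so part of these differences may come from them.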
